A study of Sus scrofa with 13 samples.

How the data were processed

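RNA sequencing libraries were made from pools of pig embryos, Sus scrofa, in 5 groups: blastocysts and hatched blastocysts developed in vivo (2 libraries each), and 4-cell embryos, blastocysts and hatched blastocysts produced by in vitro fertilisation (IVF, 3 libraries each). A blastocyst is the stage with a fluid-filled cavity, and a hatched blastocyst has left the zona pellucida that surrounds the egg. Per the labels' protocols, total RNA was extracted with TRIzol, messenger RNA was enriched on oligo(dT) beads, and libraries from an NEBNext Ultra kit were read as pairs on an Illumina HiSeq. The number of embryos in a pool, and whether libraries of a group came from different animals, fertilisation rounds or days, were not given in the sources used here. The p-values therefore measure the spread between these libraries, which may in part be technical.

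The authors deposited 1 gene table on the Sscrofa11.1 build, with read counts, FPKM and TPM for each library. The deposited counts were whole numbers, not normalised. The deposited FPKM values are fragment counts scaled by gene length and library size, as made by the authors. The submitters' processing notes name fastp 0.18.0, Bowtie2, HISAT2, StringTie 1.3.1 and RSEM, with no role or order. How the counts were made or rounded, how reads shared between near-identical genes were split, and whether strand was used were not given in the sources used here. The table had 28232 genes, of which 28208 matched a RefSeq gene table of the same build by NCBI gene number, and the gene positions come from that table. The 24 others were mitochondrial rRNA and tRNA genes, with 0.0171% to 0.112% of the counts of a library. Among the genes, 488 shared their symbol with another gene. NANOG is such a symbol, so its values are uncertain.

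The count column of 1 in vivo hatched library carried no replicate number, and it is called the unnumbered library. Of the 39 columns with values per library, 14 were not used: 13 of TPM and 1 of FPKM. Total counts lay between 33259311 and 39273867 per library, so a floor of 3 counts corresponds to 0.0764 to 0.0902 CPM. Where all libraries of a group had 0 counts, the fold is given as a lower bound against this floor, with 3 counts in each library. Where a group held 1 to 3 counts, the ratio is given with a 95% counting interval. Floors and intervals cover counting error only. Replicates differed by more than sampling noise (chi-square per degree of freedom of at least 78.3 in every pair), and all were kept as separate libraries.

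Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the edgeR filter on low counts and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. The 10 blastocyst and hatched blastocyst libraries were fitted together (15528 genes) for the comparisons of IVF with in vivo embryos, of hatched with unhatched blastocysts, and of the hatching change between origins. The 9 IVF libraries were fitted together (16312 genes) for the comparisons with 4-cell embryos. Values per group are counts scaled to library size and normalised (CPM) with the SD between libraries, and fold changes are on the log2 scale with their standard error. A printed adjusted p of a gene comes from this edgeR test. Of the named genes called, the CPM ranges of the groups compared were apart for 50 of 50 (IVF against in vivo blastocysts), 67 of 67 (hatched blastocysts), 63 of 63 (in vivo hatching), 7 of 7 (IVF hatching), 72 of 73 (blastocysts against 4-cell embryos; LTF was the exception) and 72 of 72 (hatched blastocysts against 4-cell embryos). For a gene picked without regard to its values, chance gives 20% for 2 against 3 libraries, 33.3% for 2 against 2 and 10% for 3 against 3. The named genes were picked partly because their ranges were apart or their p was small, so this tally describes them and tests nothing. With some single library left out, 24 of 50, 19 of 67, 20 of 63, 3 of 7, 2 of 73 and 2 of 72 of these genes lost their call in the same order, and 30 of 52 for the difference of hatching changes.

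The groups, tests, alternatives, 36 gene lists and the rule for named genes were fixed before the data were examined. The rule took, on each side of a comparison, the 8 called genes (5 for the difference of hatching changes) with the largest fold, a proper symbol, a mean of at least 5 CPM in the higher group and, outside that difference, group ranges that did not overlap. It added the 2 called members with the smallest p from each called list, the called member with the smallest p from other lists, and in every comparison POU5F1, NANOG, SOX2, CDX2, GATA3, GATA2, GATA4, GATA6, SOX17, DNMT3B, IGF2 and HSPA5. Lists printed as counts name up to 4 members by smallest p. Some of these genes are left to counts in the text, and some are not reported here. Other genes named are said to have been chosen after their values were seen. Lists were tested two-sided with camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of the calls of these 36 lists over the 7 comparisons, that of the cholesterol list at IVF hatching was kept with an estimated correlation, and the others were lost. Of the stage lists, that of genes higher later kept its call in hatched blastocysts. Of the 66 names in the list of nuclear oxidative phosphorylation genes, 39 were found in the table under their symbols and tested. Stage lists of up to 300 genes a side came from comparisons that shared no library with the comparison they were tested in. Overlaps of calls were tested with Fisher's exact test.

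The tests were tried on simulated counts with 40 genes changed by each of 5 fold sizes, the largest 2 of which were added after a first run. For IVF against in vivo blastocysts (14684 genes) edgeR recovered 15% of 2-fold, 60% of 4-fold and 87.5% of 8-fold changes. For in vivo hatching (14794 genes) it recovered 12.5%, 62.5% and 80%, and for IVF hatching (14801 genes) 12.5%, 72.5% and 87.5%. For IVF blastocysts against 4-cell embryos (15791 genes) it recovered 0% of 2-fold, 0% of 4-fold, 35% of 8-fold, 77.5% of 32-fold and 80% of 128-fold changes. Of its calls, 4.7%, 4.9%, 3.3% and 3.8% were false in these 4 comparisons, and of those of DESeq2 23.9%, 34.4%, 26.5% and 49.6%. The simulated counts were drawn with the spread that edgeR fitted for each gene, which may favour edgeR. The 200 changed genes were fewer than were called in the data in all but IVF hatching. Neither the false shares nor the recovered shares therefore carry over to the data. The adjusted cutoff is less strict where more genes change, so recovery may be higher in comparisons with more calls. limma-voom also recovered 0% of 2-fold changes against 4-cell embryos, and DESeq2 10%.

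Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter on low counts, a filter of at least 1 CPM in at least 2 libraries, all 13 libraries in 1 fit, only the groups compared, the replicate number as a block, a fold of at least 2, each library left out in turn, and limma-trend on log2(FPKM + 1) where both groups had numbered FPKM columns. Added after the data were seen were fits without the mitochondrial genes, a robust prior in edgeR, and IVF groups of 2 libraries at hatching.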

Results

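Messenger RNA was sequenced from pools of pig preimplantation embryos to compare stages of development and to compare embryos produced by IVF with embryos developed in vivo. Libraries of in vivo blastocysts held 38854812 and 37107530 counts (n = 2), and those of in vivo hatched blastocysts 35110201 in the unnumbered library and 37341484 in library 2 (n = 2). IVF 4-cell embryos had 33771885, 33259311 and 33689253 counts, IVF blastocysts 39273867, 38748120 and 36392910, and IVF hatched blastocysts 35631851, 38649374 and 36233473 (n = 3 each). Between 14221 and 16735 genes had a count in a library. Below, the value after ± is the SD between libraries for CPM and the standard error for a log2 fold change, with n = 2 for each in vivo group and n = 3 for each IVF group.

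Over the 10 blastocyst and hatched libraries, the first principal component (37.8% of the variance of 15805 genes) placed the in vivo hatched libraries at 55.47 and 91.07, the in vivo blastocysts at 10.03 and 23.11, and the 6 IVF libraries between -39.47 and -23.06. The second component (26.6%) placed the in vivo blastocysts at 55.05 and 78.64. Pearson correlations of log2 CPM across genes between libraries of a group were 0.981 for in vivo blastocysts, 0.983 for in vivo hatched, 0.985 to 0.989 for IVF blastocysts, 0.988 to 0.99 for IVF hatched and 0.878 to 0.953 for 4-cell embryos. With all 13 libraries, 4-cell library 1 lay at -126.43 on the second component and the other 4-cell libraries at 52.33 and 57.52.

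**Figure D1:**
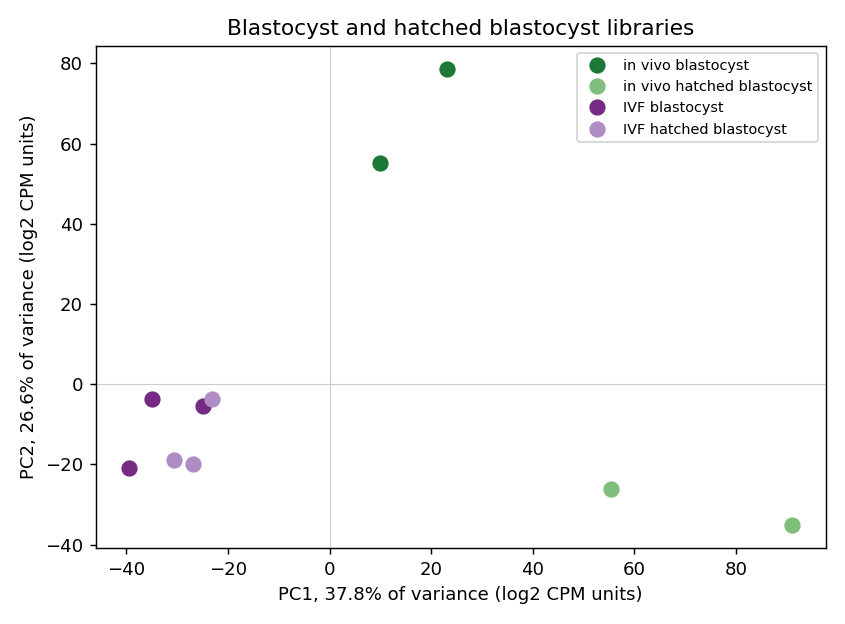
Principal components 1 (37.8% of the variance) and 2 (26.6%) of log2 CPM in the 10 blastocyst and hatched blastocyst libraries, 1 point per library, coloured by group. The 6 IVF libraries lie between -39.47 and -23.06 on component 1, and the 4 in vivo libraries between 10.03 and 91.07.

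The comparison of IVF with in vivo blastocysts described the difference between origins at this stage. Animals, embryo age, day of collection and sequencing batch may go with origin. No difference between origins below can therefore be put down to IVF or culture alone. PDIA6, a protein disulfide isomerase of the endoplasmic reticulum, or ER (gene 100499564, chromosome 3, 125752079 to 125774225, Sscrofa11.1), had 1247 ± 354 CPM in vivo and 320 ± 52.2 after IVF, a log2 fold change of -1.96 ± 0.26 (adjusted p = 0.00344). CRELD2, another ER protein, changed by -2.16 ± 0.30 (adjusted p = 0.00381). HSPA5, the main ER chaperone of the HSP70 family (gene 407060, chromosome 1, 265930044 to 265934959), had 3493 ± 857 CPM in vivo and 800 ± 250 after IVF (-2.13 ± 0.36, adjusted p = 0.00674), and without in vivo blastocyst library 1 its change was -1.84 and no longer passed. Of 29 tested genes of the unfolded protein and integrated stress response, 11 fell, and 17 fell when adjusted over the list alone (median log2 fold change -1.0). The unfolded protein list had an adjusted p of 2.08e-10 (adjusted p = 0.174 with an estimated correlation). SLC7A11, which imports cystine, had 64.9 ± 6.97 CPM in vivo and 4.28 ± 4.03 after IVF (-3.92 ± 0.60, adjusted p = 0.00456).

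Messages of the mitochondrial genome were also lower in IVF blastocysts. ND4L, a subunit of complex I, had 2145 ± 591 CPM in vivo and 245 ± 86.1 after IVF (-3.13 ± 0.50, adjusted p = 0.00496), and ND6 had 359 ± 18.2 and 94.7 ± 9.37 CPM. Of 13 such messages 7 fell, and 11 fell when adjusted over the list alone (median -1.36). The mitochondrial message list had an adjusted p of 1.14e-08 (adjusted p = 0.633 with an estimated correlation). They made up 3.64% ± 0.17 of the counts in in vivo blastocysts and 0.97% ± 0.0954 in IVF blastocysts.

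Other genes were higher in IVF blastocysts. TDGF1, a co-receptor of Nodal signalling (gene 100623389, chromosome 13, 29537874 to 29544686), rose from 30.5 ± 0.948 CPM in vivo to 277 ± 105 (3.18 ± 0.33, adjusted p = 0.00115). FADS1, a fatty acid desaturase (gene 444995, chromosome 2, 9735425 to 9747405), rose from 48.6 ± 3.12 to 269 ± 55.2 CPM (2.47 ± 0.27, adjusted p = 0.00174). The estrogen-forming enzyme HSD17B1 rose from 1.82 ± 0.621 to 156 ± 87.7 CPM (6.42 ± 0.85, adjusted p = 0.00344), and the lysosomal proteases CTSB (1.89 ± 0.27) and CTSH (2.62 ± 0.34), the tight junction gene CLDN6 (2.37 ± 0.34) and lactate dehydrogenase LDHA (1.68 ± 0.26) rose with adjusted p between 0.00327 and 0.00456. CAVIN2 was at least 156-fold and VNN2 at least 122-fold higher than in the in vivo libraries, where both had no counts. Of the cumulus and granulosa markers, EREG (2.08 ± 0.30, adjusted p = 0.00381) and CYP11A1 (7.03 ± 1.74, adjusted p = 0.0274) rose. VCAN of that list fell (-5.79 ± 1.33, adjusted p = 0.0208). Of 83 ribosomal protein genes 13 rose, and 19 when adjusted over the list alone (median 0.46). The ribosomal protein list had an adjusted p of 9.21e-06 (adjusted p = 0.718 with an estimated correlation), with RPS24 at 1.56 ± 0.22. Steroid synthesis genes rose in 5 of 13 (7 higher and 1 lower when adjusted over the list alone, median 1.41, list adjusted p = 0.0399, adjusted p = 0.633 with an estimated correlation), and the list did not pass without in vivo blastocyst library 1 (0.11) or 2 (0.109). Proteases and inhibitors studied in hatching rose in 7 of 25 (7 when adjusted over the list alone, median 0.63, list adjusted p = 0.0486, adjusted p = 0.633 with an estimated correlation), and did not pass without in vivo library 1 (0.11), in vivo library 2 (0.12) or IVF library 2 (0.11).

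In all, 945 genes were higher and 736 lower in IVF than in in vivo blastocysts by the edgeR test (4255 of 15528 at an unadjusted p under 0.05). Lineage genes POU5F1 (0.56 ± 0.27, adjusted p = 0.213), CDX2 (0.74 ± 0.42, 0.276), GATA3 (-0.87 ± 0.31, 0.0953), GATA4 (0.73 ± 0.37, 0.225) and GATA6 (0.44 ± 0.30, 0.377), and SOX2, SOX17, GATA2, DNMT3B and IGF2 (adjusted p from 0.0973 to 0.904), did not pass. NANOG had -3.55 ± 1.27 (adjusted p = 0.0966), but its symbol is shared. The count of 1681 genes was 320 without in vivo blastocyst library 1, 831 without IVF library 1 and 702 without IVF library 2, and 7 when the 4-cell libraries joined the fit.

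In hatched blastocysts, markers of the hypoblast, the layer that lines the blastocyst cavity and later forms yolk sac endoderm, were lower after IVF. COL4A2, a chain of basement membrane collagen (gene 100153454, chromosome 11, 76996885 to 77161617), had 28.8 ± 14.4 CPM in vivo and 1.65 ± 0.602 after IVF (-4.12 ± 0.44, adjusted p = 0.000353). The collagen chaperone SERPINH1 had 151 ± 81.2 and 7.17 ± 3.55 CPM (-4.40 ± 0.51, adjusted p = 0.000521). SOX17, an endoderm transcription factor (gene 100154087, chromosome 4, 76854218 to 76857143), had 53.5 ± 32.4 and 2.6 ± 2.47 CPM (-4.36 ± 0.71, adjusted p = 0.0034). Of 24 tested hypoblast genes 15 fell, and 17 when adjusted over the list alone (median -3.62, or -3.21 with genes at 0 counts held at their bound). The hypoblast list had an adjusted p of 3.24e-16 (adjusted p = 0.157 with an estimated correlation). GATA4 changed by -1.86 ± 0.35 (adjusted p = 0.00756), and by -0.99 (adjusted p = 0.126) without in vivo hatched library 2. GATA6 did not pass (0.08 ± 0.30, adjusted p = 0.902). DNMT3B, a DNA methyltransferase (gene 100302109, chromosome 17, 36345715 to 36386076), had 48.8 ± 24.5 CPM in vivo and 4.23 ± 2.85 after IVF (-3.53 ± 0.54, adjusted p = 0.00242). Of 39 genes of WNT, FGF and TGF-beta signalling 9 fell and 2 rose, against 12 and 4 when adjusted over the list alone (median -0.69). The signalling list had an adjusted p of 0.00263 (adjusted p = 0.292 with an estimated correlation), with BMP2 at -3.63 ± 0.61 and FST at -2.43 ± 0.34.

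**Figure D2:**
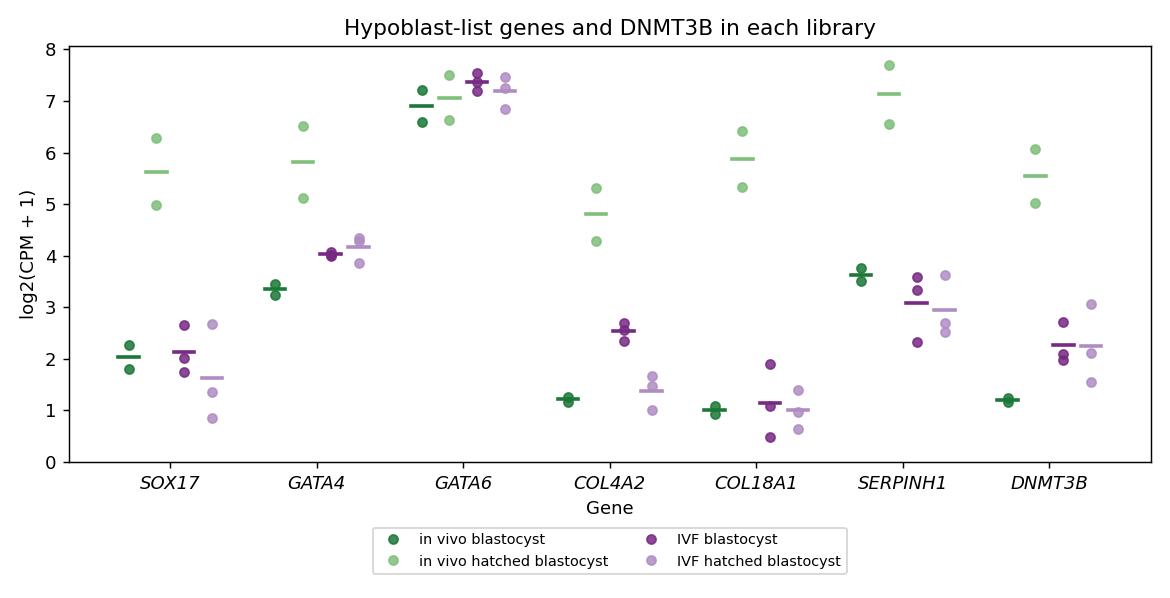
Expression of hypoblast-list genes and of DNMT3B as log2(CPM + 1) in each of the 10 blastocyst and hatched libraries, with 1 point per library and a line at the group mean. COL4A2 averaged 28.8 CPM in in vivo hatched blastocysts and 1.65 CPM in IVF hatched blastocysts, and SOX17 averaged 53.5 and 2.6 CPM.

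The lists of targets of the tumour suppressor p53 and of antioxidant genes were higher in IVF hatched blastocysts at the preset correlation. Most members did not pass over all genes. PHLDA3 (gene 100622793, chromosome 10, 23824181 to 23827428), a p53 target, rose from 212 ± 83.4 CPM in vivo to 1688 ± 399 (2.99 ± 0.30, adjusted p = 0.000234), and ZMAT3, another target, from 23.6 ± 8.23 to 205 ± 10.7 CPM (3.12 ± 0.33, adjusted p = 0.000353). Of 25 p53 targets 11 rose, and 14 when adjusted over the list alone (median 1.05). The p53 list had an adjusted p of 4.89e-11 (adjusted p = 0.119 with an estimated correlation). The quinone reductase NQO1 rose from 0.797 ± 0.0347 to 25.1 ± 6.56 CPM (4.97 ± 0.65, adjusted p = 0.00106), and glutathione synthetase GSS by 1.63 ± 0.22. Of 32 antioxidant genes 10 rose and 1 fell, against 12 and 1 when adjusted over the list alone (median 0.65). The antioxidant list had an adjusted p of 4.13e-06 (adjusted p = 0.119 with an estimated correlation). Of 31 lysosome and autophagy genes 7 rose, and 10 rose and 1 fell when adjusted over the list alone (median 0.39). The lysosome list had an adjusted p of 0.00232 (adjusted p = 0.292 with an estimated correlation). TYMS, which makes thymidylate, rose from 90.9 ± 0.916 to 421 ± 19 CPM (2.21 ± 0.18, adjusted p = 0.000116). ACPP was at least 121-fold and TMPRSS13 at least 73.3-fold higher, with no counts in the in vivo hatched libraries.

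The lists of heat shock proteins, of the unfolded protein and integrated stress response and of mitochondrial messages were lower in IVF hatched blastocysts. BAG3, a co-chaperone of HSP70 (gene 100156989, chromosome 14, 129510240 to 129533998), had 137 ± 22.9 CPM in vivo and 16.1 ± 2.75 after IVF (-3.10 ± 0.26, adjusted p = 0.00012), and HSP70.2 had 2953 ± 412 and 350 ± 77.7 CPM (-3.08 ± 0.29, adjusted p = 0.000211). HSP70.2 (chromosome 7, 23925929 to 23927854) lies within the span of HSPA1L (23909960 to 23938678). How reads shared between such genes were split is not known, so its counts are uncertain. Of 23 heat shock genes 6 fell, and 7 when adjusted over the list alone (median -0.48). The heat shock list had an adjusted p of 4.13e-06 (adjusted p = 0.278 with an estimated correlation). Of 29 unfolded protein response genes 13 fell, and 16 when adjusted over the list alone (median -0.97). The unfolded protein list had an adjusted p of 2.78e-08 (adjusted p = 0.119 with an estimated correlation), with HSPA5 at -1.88 ± 0.36 and HYOU1 at -1.91 ± 0.32. Of 13 mitochondrial messages 11 fell, and 11 when adjusted over the list alone (median -2.01). The mitochondrial message list had an adjusted p of 1.37e-10 (adjusted p = 0.292 with an estimated correlation), with ND4L at -3.02 ± 0.50. Their share was 1.49% in the unnumbered in vivo hatched library, 6.85% in in vivo library 2, and 0.823% ± 0.191 in IVF hatched blastocysts.

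**Figure D3:**
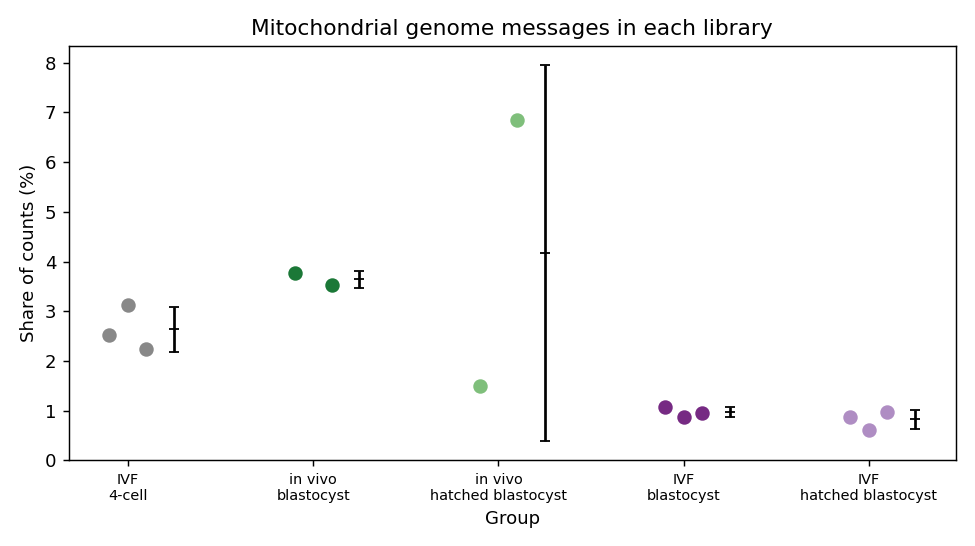
Share of counts (%) from the messages of the mitochondrial genome in each of the 13 libraries, 1 point per library, with the group mean and an SD bar beside the points. The in vivo hatched libraries lie at 1.49% and 6.85%, and the 6 IVF blastocyst and hatched libraries between 0.61% and 1.07%.

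The lists of cell cycle and of genome activation genes were lower in IVF hatched blastocysts at the preset correlation, though most members did not pass. MCM7 (-1.14 ± 0.18, adjusted p = 0.00264) and MCM3 (-1.53 ± 0.26, adjusted p = 0.00402), subunits of the replicative helicase, were among 10 of 34 cell cycle genes that fell while 2 rose, against 12 and 2 when adjusted over the list alone (median -0.55). The cell cycle list had an adjusted p of 0.00106 (adjusted p = 0.368 with an estimated correlation). MYC changed by -1.90 ± 0.33, and of 20 genes of embryonic genome activation 5 fell, and 8 when adjusted over the list alone (median -0.56). The genome activation list had an adjusted p of 0.000405 (adjusted p = 0.192 with an estimated correlation). Of 30 regulators of DNA methylation and chromatin 3 fell, and 4 when adjusted over the list alone (median -0.42). The chromatin list had an adjusted p of 0.0185 (adjusted p = 0.292 with an estimated correlation), and this list did not pass without in vivo hatched library 2 (0.143). The bile acid transporter family member SLC10A4 had 53.8 ± 13.7 CPM in vivo and 0.149 ± 0.157 after IVF.

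Between hatched blastocysts of the 2 origins, 1081 genes were higher and 758 lower after IVF by the edgeR test (4278 at an unadjusted p under 0.05). POU5F1 was at 1.13 ± 0.28 (adjusted p = 0.0239) and lost its call without in vivo library 2 (0.78), IVF library 2 (1.04) or IVF library 3 (1.07), and CDX2, GATA3, GATA2, SOX2 and IGF2 did not pass (adjusted p from 0.149 to 0.937). NANOG, whose symbol is shared, had 6.9 ± 0.987 CPM in vivo and 0.232 ± 0.235 after IVF (-4.88 ± 1.36, adjusted p = 0.039). Its call was lost without the unnumbered in vivo library (-5.01), in vivo library 2 (-4.74) or IVF library 1 (-4.86), 2 (-5.91) or 3 (-4.29). The count of 1839 genes was 513 without in vivo hatched library 2, 1046, 1072 and 984 without IVF hatched library 1, 2 and 3, and 92 when the 4-cell libraries joined the fit. Marker lists for other cell types did not pass in this comparison, with adjusted p of 0.963 for oviduct and uterine epithelium, 0.319 for stroma and vessel, 0.257 for blood and immune cells, 0.536 for cumulus and granulosa cells and 0.879 for sperm.

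The 2 comparisons of IVF with in vivo embryos share no library, but both come from 1 fit with the same estimated spread for each gene. A gene of small spread is then more readily called at both stages. Fisher's test also treats genes as independent, so its p-values here are descriptive. Of the genes called higher after IVF, 257 were called at both stages, where 65.8 were expected (Fisher's exact test, p = 6.85e-90), and of those called lower 115 were, where 35.9 were expected (p = 8.53e-30). Across all 15528 genes, which are not independent replicates, the log2 fold changes of the 2 stages had a Pearson correlation of 0.18 and a Spearman correlation of 0.23. Over the 4511 genes with an average log2 CPM above 5 the Pearson correlation was 0.32. Stage lists were picked from IVF libraries of the other stage, so genes that are higher after IVF at both stages enter the lists of genes higher later, and genes that are lower at both enter those of genes higher in 4-cell embryos. Their direction is therefore not independent evidence of a difference in stage. Genes that were higher in IVF hatched blastocysts than in 4-cell embryos were tested as a list of 300 in IVF against in vivo blastocysts, where 73% were higher (51.8% of all genes), and 69 rose and 11 fell (median 0.67, list adjusted p = 7.07e-09, adjusted p = 0.0776 with an estimated correlation). For hatched blastocysts the list came from IVF blastocysts against 4-cell embryos, and 79% of its 300 genes were higher after IVF (51.6% of all genes), with 120 rising and 14 falling (median 1.24, list adjusted p = 7.84e-23, adjusted p = 0.0086 with an estimated correlation). The list of genes higher in 4-cell embryos did not pass in blastocysts (2 of 300 rose, median 0.22, list adjusted p = 0.814). In hatched blastocysts it was lower after IVF, with 14 of its 300 genes falling and 1 rising (median -0.54, list adjusted p = 0.0128, adjusted p = 0.358 with an estimated correlation), a call lost without in vivo library 2 (0.114) or IVF library 2 (0.0698).

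Hatching in vivo was compared by setting hatched against unhatched in vivo blastocysts. Hypoblast genes rose. COL4A2 rose from 1.32 ± 0.128 to 28.8 ± 14.4 CPM (4.44 ± 0.53, adjusted p = 0.000889), COL18A1, which gives a basement membrane collagen, from 1.01 ± 0.156 to 61.8 ± 32.1 CPM (5.94 ± 0.85, adjusted p = 0.00188), and GATA4 from 9.26 ± 1.08 to 62.1 ± 40.1 CPM (2.75 ± 0.42, adjusted p = 0.00234). Of 24 hypoblast genes 11 rose, and 14 when adjusted over the list alone (median 2.67). The hypoblast list had an adjusted p of 1.28e-08 (adjusted p = 0.266 with an estimated correlation). SOX17 rose by 4.08 ± 0.83 (adjusted p = 0.00869), and without in vivo blastocyst library 1 (3.85) or hatched library 2 (3.29) it did not pass. DNMT3B rose from 1.29 ± 0.0916 to 48.8 ± 24.5 CPM (5.23 ± 0.69, adjusted p = 0.00126), the ligand BMP2 by 5.14 ± 0.78, and ASCL2, a trophoblast transcription factor, by 8.19 ± 1.05.

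The cell cycle list was higher after hatching in vivo at the preset correlation, though most members did not pass over all genes. The mitotic kinase PLK1 rose from 60.3 ± 6.02 to 284 ± 48 CPM (2.23 ± 0.27, adjusted p = 0.000889) and MCM4 from 54.3 ± 3.57 to 182 ± 13.9 CPM (1.75 ± 0.22, adjusted p = 0.000899). Of 34 cell cycle genes 12 rose and 2 fell, against 17 and 3 when adjusted over the list alone (median 1.00). The cell cycle list had an adjusted p of 5.73e-06 (adjusted p = 0.253 with an estimated correlation). Of 23 heat shock genes 5 rose and 1 fell, against 9 and 2 when adjusted over the list alone (median 0.62). The heat shock list had an adjusted p of 0.00378 (adjusted p = 0.471 with an estimated correlation), with DNAJB1 at 2.13 ± 0.36. Of 23 glycolysis genes 6 rose, and 7 rose and 2 fell when adjusted over the list alone (median 0.39). The glycolysis list had an adjusted p of 0.0311 (adjusted p = 0.253 with an estimated correlation), with HK1 at 2.95 ± 0.42 and PKM at 1.98 ± 0.28, and the list did not pass without in vivo blastocyst library 1 (0.195) or the unnumbered hatched library (0.172). Of 20 genome activation genes 4 rose, and 4 when adjusted over the list alone (median 0.49, or 0.44 with genes at 0 counts held at their bound). The genome activation list had an adjusted p of 0.0311 (adjusted p = 0.396 with an estimated correlation), with NCL at 2.67 ± 0.44, and the list did not pass without blastocyst library 2 (0.146) or hatched library 2 (0.0879). Of 8 cumulus and granulosa cell markers 3 rose, and 3 when adjusted over the list alone (median 0.69). The cumulus and granulosa list had an adjusted p of 0.0375 (adjusted p = 0.253 with an estimated correlation), among them EREG (2.94 ± 0.32). That list did not pass without blastocyst library 1 (0.384) or 2 (0.146), or without the unnumbered hatched library (0.158) or hatched library 2 (0.264).

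The lists of cholesterol genes, antioxidants and p53 targets were lower after hatching in vivo at the preset correlation. Most antioxidant and p53 members did not pass over all genes. SC5D, an enzyme late in cholesterol synthesis (gene 100520925, chromosome 9, 48357115 to 48372391), had 287 ± 38.4 CPM before and 49.3 ± 6.75 after (-2.54 ± 0.24, adjusted p = 0.000306), and INSIG1, a regulator of sterol synthesis, 183 ± 13.8 and 25.5 ± 3.99 CPM (-2.84 ± 0.34, adjusted p = 0.000889). Of 22 cholesterol genes 12 fell, and 16 fell and 1 rose when adjusted over the list alone (median -1.36). The cholesterol list had an adjusted p of 1.12e-12 (adjusted p = 0.253 with an estimated correlation). SLC7A11 had 64.9 ± 6.97 CPM before and 0.653 ± 0.0779 after (-6.63 ± 0.81, adjusted p = 0.000889). Of 32 antioxidant genes 12 fell and 2 rose, against 16 and 4 when adjusted over the list alone (median -0.68). The antioxidant list had an adjusted p of 0.00199 (adjusted p = 0.253 with an estimated correlation), a list call lost without hatched library 2 (0.0615). CDKN1A, an inhibitor of cyclin-dependent kinases, changed by -3.04 ± 0.47 (adjusted p = 0.00254) and ZMAT3 by -1.90 ± 0.33, and of 25 p53 targets 8 fell, and 8 when adjusted over the list alone (median -0.78). The p53 list had an adjusted p of 8.5e-05 (adjusted p = 0.253 with an estimated correlation). TYMS (-2.39 ± 0.20) and the amino acid transporter SLC7A5 (-3.19 ± 0.34) were among 7 of 30 genes of amino acid transport and one-carbon metabolism that fell while 1 rose, against 10 and 1 when adjusted over the list alone (median -0.07). The amino acid list had an adjusted p of 0.00619 (adjusted p = 0.396 with an estimated correlation). That list did not pass without blastocyst library 2 (0.135) or the unnumbered hatched library (0.238). Of 39 nuclear genes of oxidative phosphorylation 2 fell (median -0.36). The oxidative phosphorylation list had an adjusted p of 0.0206 (adjusted p = 0.761 with an estimated correlation). These were NDUFB9 (-0.80 ± 0.23) and NDUFB11 (-1.22 ± 0.35), which did not pass when adjusted over the list alone. The list did not pass without blastocyst library 1 (0.918) or hatched library 2 (0.366). NDUFB9 was at -0.53 and -0.58 without these libraries and lost its call. NDUFB11 lost it as well (-0.78 and -1.12), and also without the unnumbered library (-1.31).

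In vivo, 1080 genes were higher and 1148 lower in hatched than in unhatched blastocysts by the edgeR test (4735 at an unadjusted p under 0.05). IL6, a cytokine, had 84.4 ± 41 CPM before and 1.31 ± 0.726 after (-6.00 ± 0.65, adjusted p = 0.000539), and CASQ2 changed by -6.33 ± 0.56. PAG6, a pregnancy-associated glycoprotein, was at least 111-fold lower, but it belongs to a family of similar genes and its counts are uncertain. HSPA5 (0.09 ± 0.40, adjusted p = 0.917), POU5F1 (-0.86 ± 0.30, 0.0743), CDX2 (1.21 ± 0.45, 0.095), SOX2, NANOG, GATA2, GATA6 and IGF2 did not pass. The count of 2228 genes was 1064 without blastocyst library 1, 1086 without hatched library 2, 757 when the 4 in vivo libraries were fitted alone and 101 when the 4-cell libraries joined the fit.

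The same comparison within IVF called 7 genes, all lower in hatched blastocysts and all in the list of cholesterol genes. FDFT1, or squalene synthase (gene 100312971, chromosome 14, 14976259 to 15010701), had 111 ± 36.6 CPM in blastocysts and changed by -3.33 ± 0.32 (adjusted p = 0.00237). MSMO1, a sterol oxidase (gene 396590, chromosome 8, 43726834 to 43745784), had 528 ± 176 and 60.8 ± 16.5 CPM (-3.12 ± 0.32, adjusted p = 0.00292). INSIG1 (gene 403162, chromosome 18, 2885494 to 2898758) had 167 ± 41 and 22 ± 6.85 CPM (-2.93 ± 0.28, adjusted p = 0.00237), and HMGCS1, which feeds the pathway with HMG-CoA (gene 100524223, chromosome 16, 27936225 to 27957261), 256 ± 35.9 and 55 ± 9.81 CPM (-2.22 ± 0.22, adjusted p = 0.00249). Lower as well were CYP51 (gene 403334, chromosome 9, 72057506 to 72079587, -2.86 ± 0.39, adjusted p = 0.0284) and FDPS (gene 100153932, chromosome 4, 94500140 to 94514820, -1.88 ± 0.23, adjusted p = 0.00999). CYP51 lost its call without IVF blastocyst library 1 (-2.74) or 3 (-2.81) or hatched library 3 (-2.85), and FDPS without blastocyst library 1 (-1.76) or 3 (-1.83) or hatched library 1 (-1.78) or 3 (-1.81). Of 22 cholesterol genes 7 fell, and 20 when adjusted over the list alone (median -1.68). The cholesterol list had an adjusted p of 3.1e-110 (adjusted p = 0.0024 with an estimated correlation).

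**Figure D4:**
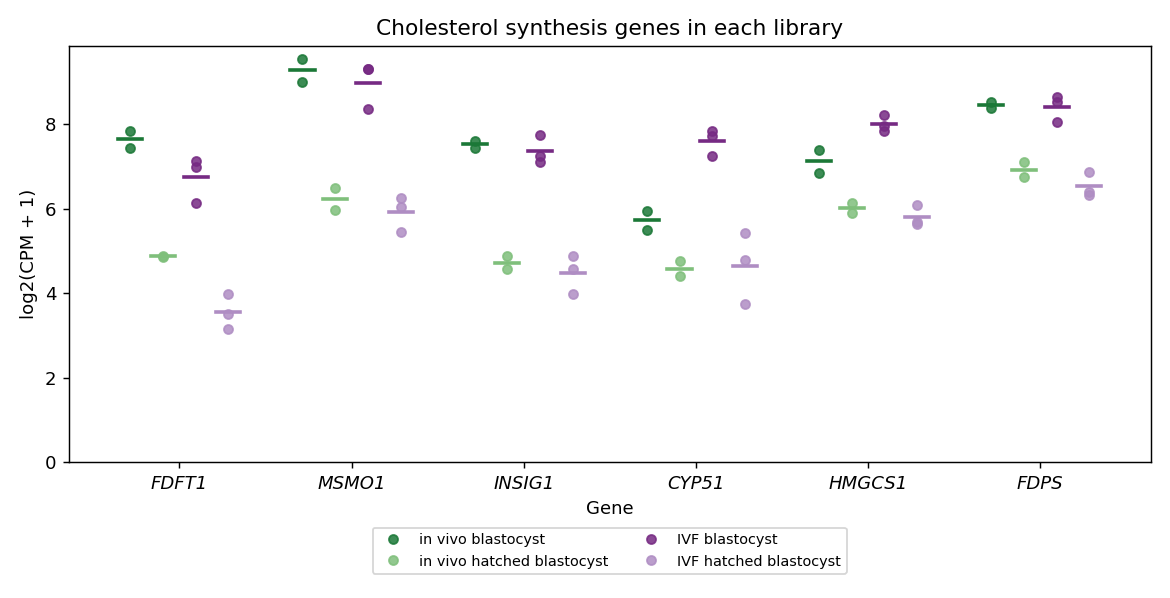
Expression of cholesterol genes as log2(CPM + 1) in each of the 10 blastocyst and hatched libraries, with 1 point per library and a line at the group mean. MSMO1 averaged 528 CPM in IVF blastocysts and 60.8 CPM in IVF hatched blastocysts, and INSIG1 averaged 167 and 22 CPM.

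No gene was called higher in IVF hatched than in IVF blastocysts by edgeR, and 594 genes in both directions had an unadjusted p under 0.05. DESeq2 called 13 higher and 38 lower, and limma-voom called 7, all lower. The count of 7 was 4 without IVF blastocyst library 1 and 4 without library 3, 162 without a filter on low counts, and 0 when the 4-cell libraries joined the fit, where 430 genes had an unadjusted p under 0.05. POU5F1, CDX2, GATA3 and HSPA5 were at -0.29 ± 0.24, 0.63 ± 0.36, 0.16 ± 0.28 and 0.34 ± 0.33.

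A further 7 lists shifted at IVF hatching, though no single member passed by edgeR. TCA cycle genes had a median of 0.24 (list adjusted p = 7.57e-05, adjusted p = 0.701 with an estimated correlation), and the list had 0.0568 without hatched library 2. Antioxidants had a median of 0.30 (list adjusted p = 0.0024, adjusted p = 0.501 with an estimated correlation), and 0.0889 without blastocyst library 2. Cumulus and granulosa markers had 1.05 (list adjusted p = 0.0154, adjusted p = 0.371 with an estimated correlation), a call lost without blastocyst library 3 (0.0911) or hatched library 1 (0.0688). Ribosomal protein genes had a median of -0.29 (list adjusted p = 6.04e-12, adjusted p = 0.875 with an estimated correlation). Oocyte and maternal genes had -1.51, or -0.61 with genes at 0 counts held at their bound. Their adjusted p was 0.00165 (adjusted p = 0.639 with an estimated correlation) and 0.427 without blastocyst library 1. Amino acid genes had -0.21 (list adjusted p = 0.0278, adjusted p = 0.833 with an estimated correlation), a call lost without blastocyst library 3 (0.671), hatched library 1 (0.0688) or hatched library 2 (0.0544). Mitochondrial messages had -0.43 (list adjusted p = 0.0424, adjusted p = 0.875 with an estimated correlation), a call lost without blastocyst library 1 (0.456) or 3 (0.0555) or hatched library 2 (0.666).

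Of the genes called at hatching, 5 were lower in both origins, where 0.518 were expected (Fisher's exact test, p = 4.05e-05). Both comparisons come from 1 fit and all 5 genes are in the cholesterol list, so this p is descriptive. The 5 genes were FDFT1 (-2.83 in vivo), MSMO1 (-3.05), INSIG1 (-2.84), HMGCS1 (-1.14) and FDPS (-1.52), chosen after their values were seen. CYP51 (-1.18, adjusted p = 0.102) did not pass in vivo. Across all genes the changes at hatching of the 2 origins had a Pearson correlation of 0.03 and a Spearman correlation of 0.08, and over the 4511 genes with an average log2 CPM above 5 a Pearson correlation of 0.2.

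The difference between the 2 hatching changes was tested directly. The hypoblast list had a lower change in IVF than in vivo. COL4A2 had a difference of -5.99 ± 0.65 (adjusted p = 0.00153), with 4.83 ± 0.676 CPM before and 1.65 ± 0.602 after hatching in IVF, and COL18A1 of -6.36 ± 0.99 (adjusted p = 0.00781), with 1.41 ± 1.18 and 1.05 ± 0.531 CPM. DNMT3B had -5.13 ± 0.80 (adjusted p = 0.00781), with 3.92 ± 1.44 and 4.23 ± 2.85 CPM in IVF, and BMP2 -8.11 ± 0.97 (adjusted p = 0.00225), with 8.02 ± 2.42 and 1.02 ± 0.59 CPM. The IVF hatching change of COL4A2 (adjusted p = 0.738), COL18A1 (1), DNMT3B (1) and BMP2 (0.272) did not pass. Of 24 hypoblast genes 6 had a negative difference that passed, and 10 when adjusted over the list alone (median -2.57). The hypoblast list had an adjusted p of 1.33e-10 (adjusted p = 0.383 with an estimated correlation). PLK1 (-2.09 ± 0.33) and MCM4 (-1.75 ± 0.27) were among 7 of 34 cell cycle genes with a negative difference, while 1 was positive, against 10 and 1 when adjusted over the list alone (median -0.91). The cell cycle list had an adjusted p of 7.25e-05 (adjusted p = 0.476 with an estimated correlation). Differences were positive for TYMS (2.40 ± 0.24, adjusted p = 0.00153), SLC7A11 (6.98 ± 0.93, adjusted p = 0.00401), CDKN1A (3.04 ± 0.58, adjusted p = 0.0169) and the iron store FTH1 (2.78 ± 0.36, adjusted p = 0.00343). TYMS had 477 ± 29.9 and 90.9 ± 0.916 CPM before and after hatching in vivo, and 419 ± 25.8 and 421 ± 19 CPM in IVF.

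The difference passed for 433 genes with a positive and 299 with a negative sign (3403 at an unadjusted p under 0.05). The count of 732 was 363 without in vivo blastocyst library 1, 367 without in vivo hatched library 2, 390, 453 and 343 without IVF blastocyst library 1, 2 and 3, 416, 333 and 418 without IVF hatched library 1, 2 and 3, and 1 when the 4-cell libraries joined the fit.

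IVF blastocysts were compared with IVF 4-cell embryos to describe development in culture. Epithelial and trophectoderm genes, those of the outer layer that forms placenta, were higher in blastocysts. KRT18, a keratin of simple epithelia (gene 100126286, chromosome 5, 18217686 to 18221432), had no counts in 4-cell embryos and 3357 ± 197 CPM in blastocysts, at least 42134-fold higher (adjusted p = 1.65e-05). The endocytic adaptor DAB2 rose from 1.26 ± 0.641 to 1213 ± 106 CPM (9.90 ± 0.61), and CDX2, a trophectoderm transcription factor, was at least 288-fold higher. Of 29 trophectoderm genes 16 rose and 3 fell, against 17 and 3 when adjusted over the list alone (median 3.91, list adjusted p = 6.17e-05, adjusted p = 0.154 with an estimated correlation). Of 31 genes of junctions and transport 19 rose and 4 fell, as they did when adjusted over the list alone (median 2.96, list adjusted p = 3.16e-05, adjusted p = 0.112 with an estimated correlation), with DSG2, a desmosomal cadherin, at least 3488-fold higher. Oocyte and maternal genes were lower. BMP15, an oocyte growth factor (gene 448811, chromosome X, 44613122 to 44620575), had 10015 ± 2688 CPM in 4-cell embryos and 1.57 ± 1.63 in blastocysts (-12.64 ± 1.32, adjusted p = 0.000126), and PADI6, a component of the oocyte cytoplasm, was at least 16632-fold lower. Of 34 oocyte genes 32 fell and 1 rose, as they did when adjusted over the list alone (median -10.91, or -9.59 with genes at 0 counts held at their bound, list adjusted p = 2.74e-11, adjusted p = 0.186 with an estimated correlation).

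The lists of nuclear oxidative phosphorylation, ribosomal protein and cholesterol genes were higher in blastocysts than in 4-cell embryos. NDUFA5, a subunit of complex I, rose from 0.849 ± 0.108 to 106 ± 14.2 CPM (6.96 ± 0.35, adjusted p = 1.65e-05), and of 39 nuclear genes of oxidative phosphorylation 34 rose and 1 fell, and 34 and 1 when adjusted over the list alone (median 3.55, list adjusted p = 2.55e-14, adjusted p = 0.112 with an estimated correlation). RPL7 rose by 3.77 ± 0.28, and of 83 ribosomal protein genes 68 rose, and 72 when adjusted over the list alone (median 2.70, list adjusted p = 2.53e-11, adjusted p = 0.35 with an estimated correlation). SC5D rose by 6.70 ± 0.43, and of 22 cholesterol genes 18 rose and 1 fell, and 18 and 1 when adjusted over the list alone (median 2.98, list adjusted p = 4.29e-05, adjusted p = 0.198 with an estimated correlation).

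Other lists were also higher in blastocysts than in 4-cell embryos. TCA cycle genes rose in 21 of 29 and fell in 1 (list adjusted p = 2.38e-05, adjusted p = 0.119 with an estimated correlation). Lysosome and autophagy genes rose in 19 of 31 and fell in 3 (list adjusted p = 3.6e-05, adjusted p = 0.112 with an estimated correlation). Antioxidants rose in 18 of 32 and fell in 6 (list adjusted p = 7.36e-05, adjusted p = 0.112 with an estimated correlation). Glycolysis genes rose in 16 of 23 and fell in 5 (list adjusted p = 0.000432, adjusted p = 0.112 with an estimated correlation). Steroid synthesis genes rose in 10 of 13 and fell in 1 (list adjusted p = 0.000794, adjusted p = 0.112 with an estimated correlation). Genes of solute handling of the yolk-sac type rose in 10 of 20 and fell in 3 (list adjusted p = 0.00846, adjusted p = 0.112 with an estimated correlation). Proteases rose in 13 of 25 and fell in 2 (list adjusted p = 0.0217, adjusted p = 0.198 with an estimated correlation). Targets of p53 rose in 14 of 25 and fell in 3 (list adjusted p = 0.029, adjusted p = 0.198 with an estimated correlation). Amino acid genes rose in 16 of 30 and fell in 7 (list adjusted p = 0.0351, adjusted p = 0.348 with an estimated correlation). Their call was lost without IVF blastocyst library 3 (0.0738), 4-cell library 1 (0.0553) or 4-cell library 3 (0.0586). Adjusted over the list alone, 2 TCA cycle genes fell and 11 solute genes rose, and the other counts of these lists were the same.

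In blastocysts against 4-cell embryos 4190 genes were higher and 4995 lower of 16312 by the edgeR test. SOX2 (-5.24 ± 1.3, adjusted p = 0.00817), GATA4 (-3.35 ± 0.59, adjusted p = 0.00159), DNMT3B (-2.81 ± 0.62, adjusted p = 0.00471) and DNMT3A (-4.68 ± 0.35) were lower in blastocysts, GATA2 was higher (10.34 ± 1.42, adjusted p = 0.000478), and POU5F1 (0.92 ± 0.41, adjusted p = 0.085), GATA6 (2.56 ± 1.3, 0.121), HSPA5 (1.20 ± 0.59, 0.111) and IGF2 (0.42 ± 0.89, 0.707) did not pass. NANOG was lower (-5.46 ± 1.62, adjusted p = 0.018), a call lost without IVF blastocyst library 1 (-5.29). With upper-quartile factors the median of all genes moved by -0.16, so changes below that size depend on the scaling.

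IVF hatched blastocysts were set against the same 3 4-cell libraries, in the same fit, so likeness to the comparison of blastocysts comes in part from shared libraries. By the edgeR test 4190 genes were higher and 5040 lower. KRT18 was at least 31377-fold and RGN, a calcium-binding protein, at least 34422-fold higher, and DAB2 rose by 10.20 ± 0.62. The oocyte kinase WEE2 was at least 60347-fold lower, the oocyte linker histone H1FOO at least 26140-fold and BTG4, which promotes decay of maternal messages, at least 18464-fold. BMP15, with few counts in hatched blastocysts, was lower by a ratio of 334532 (95% counting interval 114470 to 1622178). Of 34 oocyte genes 32 fell and 1 rose, and 33 and 1 when adjusted over the list alone (median -11.87, or -11.14 with genes at 0 counts held at their bound, list adjusted p = 2.79e-12, adjusted p = 0.185 with an estimated correlation). COX1 changed by -2.37 ± 0.39 (adjusted p = 0.00122), and of 13 mitochondrial messages 11 fell, and 11 when adjusted over the list alone (median -1.39, list adjusted p = 0.024, adjusted p = 0.534 with an estimated correlation).

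Nuclear genes of oxidative phosphorylation rose in 34 of 39 and fell in 1 in hatched blastocysts against 4-cell embryos (median 3.63, list adjusted p = 1.6e-14, adjusted p = 0.115 with an estimated correlation). Ribosomal protein genes rose in 62 of 83 (median 2.37, list adjusted p = 1.41e-09, adjusted p = 0.489 with an estimated correlation). Trophectoderm genes rose in 16 of 29 and fell in 3 (median 3.60, list adjusted p = 0.000172, adjusted p = 0.185 with an estimated correlation). Genes of junctions and transport rose in 19 of 31 and fell in 3 (median 2.86, list adjusted p = 3.63e-05, adjusted p = 0.115 with an estimated correlation). NDUFA5 rose by 6.95 ± 0.35.

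In the same comparison TCA cycle genes rose in 22 of 29 and fell in 2 (list adjusted p = 4.46e-06, adjusted p = 0.115 with an estimated correlation). Antioxidants rose in 20 of 32 and fell in 6 (list adjusted p = 3.63e-05, adjusted p = 0.111 with an estimated correlation). Lysosome and autophagy genes rose in 18 of 31 and fell in 3 (list adjusted p = 4.08e-05, adjusted p = 0.111 with an estimated correlation). Glycolysis genes rose in 16 of 23 and fell in 5 (list adjusted p = 0.000717, adjusted p = 0.111 with an estimated correlation). Steroid synthesis genes rose in 10 of 13 and fell in 1 (list adjusted p = 0.00112, adjusted p = 0.115 with an estimated correlation). Solute handling genes rose in 11 of 20 and fell in 2 (list adjusted p = 0.0078, adjusted p = 0.115 with an estimated correlation). Proteases rose in 13 of 25 and fell in 2 (list adjusted p = 0.0124, adjusted p = 0.185 with an estimated correlation). Targets of p53 rose in 13 of 25 and fell in 3 (list adjusted p = 0.0235, adjusted p = 0.185 with an estimated correlation). Adjusted over the list alone, 35 oxidative phosphorylation, 67 ribosomal protein, 17 trophectoderm, 19 lysosome and 14 p53 genes rose, and the other counts of the lists in hatched blastocysts were the same. NANOG was lower (-6.75 ± 1.73, adjusted p = 0.00937). POU5F1 (0.65 ± 0.41, adjusted p = 0.209) did not pass, and the median of all genes moved by -0.19 with upper-quartile factors.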

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

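The tests of explanations were chosen after the data were seen, and for the fits with IVF groups of 2 libraries the possible outcomes were set down before those fits were run. The change at hatching differed between IVF and in vivo embryos in 732 genes by a direct test of the difference. That count was 363 without in vivo blastocyst library 1, 367 without in vivo hatched library 2, 390, 453 and 343 without IVF blastocyst library 1, 2 and 3, and 416, 333 and 418 without IVF hatched library 1, 2 and 3. The direct test also passed for lists of the hypoblast (adjusted p = 1.33e-10), antioxidants (3.39e-05), p53 targets (3.39e-05), the cell cycle (7.25e-05), the TCA cycle (0.000929), ribosomal proteins (0.0013), nuclear oxidative phosphorylation (0.00854), heat shock proteins (0.0133), epithelial junctions (0.0499) and glycolysis (0.0499). With an estimated correlation their adjusted p were 0.383, 0.383, 0.383, 0.476, 0.594, 0.702, 0.702, 0.594, 0.594 and 0.383.

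Adjusted over the list alone, 12 antioxidant genes had a positive and 1 a negative difference (7 positive over all genes), 7 p53 targets a positive one (4), 10 TCA cycle genes a positive and 1 a negative one (8 and 1), 2 heat shock genes a negative one (2), 3 junction genes a negative and 1 a positive one (2 and 1) and 7 glycolysis genes a negative one (4). The oxidative phosphorylation list had a median of 0.40 though no single member passed by edgeR. The ribosomal list had a median of -0.41 and 2 negative members over all genes. Several of these list calls rested on single libraries. The junction list had 0.155 without in vivo blastocyst library 1, 0.172 without in vivo hatched library 2, 0.134 without IVF blastocyst library 2, 0.0667 without IVF hatched library 2 and 0.0589 without IVF hatched library 3. The glycolysis list had 0.294 and 0.109 without in vivo blastocyst library 1 and 2, 0.279 without the unnumbered in vivo hatched library, 0.0804 without IVF blastocyst library 1, and 0.0956 and 0.0589 without IVF hatched library 1 and 3. Oxidative phosphorylation had 0.628 without in vivo blastocyst library 1, 0.214 without in vivo hatched library 2 and 0.0667 without IVF hatched library 2, and the ribosomal list had 0.423 without the unnumbered in vivo hatched library.

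The genes with the largest fitted differences of the hatching change were PAG6 (11.26), CYP19A3 (11.22), TMPRSS13 (9.10), ADAMTS8 (9.07) and ACPP (8.13) on the positive side, and IFITM3 (-15.43), ENTPD1 (-13.79), SOX21 (-13.23), JAM3 (-12.06) and SRPK3 (-9.66) on the negative side. All but SRPK3 had a group without counts, so these log2 values depend on the fit and are no bounds. ADAMTS8 kept its call without each library in turn. The others lost theirs without in vivo hatched library 2, with PAG6 then at 11.26, CYP19A3 at 11.21, TMPRSS13 at 9.09, ACPP at 8.12, IFITM3 at -11.75, ENTPD1 at -12.59, SOX21 at -12.74, JAM3 at -11.07 and SRPK3 at -9.99. Without in vivo blastocyst library 1, IFITM3 (-15.45), ENTPD1 (-13.81), SOX21 (-13.25), JAM3 (-11.12) and SRPK3 (-8.74) also lost theirs. CYP19A3 did so without in vivo blastocyst library 2 (9.58), the unnumbered in vivo hatched library (11.22), IVF blastocyst library 2 (11.12) and IVF hatched library 2 (10.42) or 3 (11.30). IFITM3 did so without in vivo blastocyst library 2 (-15.42), and SRPK3 without the unnumbered library (-9.25) or IVF blastocyst library 3 (-9.57). Without IVF blastocyst library 1 and 3, the values of genes that lost calls were -12.96 and -15.85 for IFITM3, -14.32 and -10.65 for ENTPD1 and -10.81 and -12.20 for JAM3. Without IVF hatched library 1, 2 and 3 they were -14.94, -18.15 and -14.91 for IFITM3, -13.81, -13.81 and -13.79 for ENTPD1 and -12.07, -12.08 and -12.06 for JAM3.

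Hypoblast genes were lower in IVF than in in vivo hatched blastocysts. Maternal cells seen through 65 of 89 markers of other cell types are argued against as the source of this difference. These markers, under 1 CPM in every IVF hatched library, summed to 11.5 CPM in vivo, or 0.148% of the hypoblast excess of 7804 CPM. The other markers were left out as IVF embryos express them. Of the markers outside that sum, the vessel marker PECAM1 went with the hypoblast genes. It had 11 CPM in the unnumbered in vivo hatched library, 49.6 in library 2 and 5.78, 1.71 and 4.44 in IVF hatched libraries 1, 2 and 3. The vessel markers CDH5, VWF and KDR had no counts in either in vivo hatched library. VCAN of the cumulus and granulosa list went the same way as PECAM1, with 17.1 ± 10.3 CPM in vivo and 0.97 ± 0.858 in IVF (-4.14 ± 1.18, adjusted p = 0.0431). FCER1G and MYH11 went the opposite way. Cells seen only through such markers stay untested by the sum. Without either in vivo hatched library the list had an adjusted p of at most 1.54e-11 at the preset correlation. Such fits leave 1 in vivo library in the group, so this p cannot decide whether a single in vivo library is the cause. In the unnumbered in vivo hatched library and library 2, COL4A2 had 18.6 and 39 CPM, and SOX17 30.6 and 76.4. The IVF hatched libraries had at most 2.19 CPM of COL4A2 and 5.43 of SOX17. GATA6 showed no such gap, with 98.1 and 180 CPM in vivo and 114 to 176 in IVF. Before hatching, COL4A2 was higher in IVF blastocysts (4.83 ± 0.676 CPM) than in in vivo blastocysts (1.32 ± 0.128 CPM, 1.87 ± 0.46, adjusted p = 0.0261). SOX17, GATA4 and GATA6 did not pass there. A difference in embryo age, day of collection or sequencing batch goes with the origin and was not tested. A lower share or later formation of hypoblast in IVF embryos stays open as a hypothesis.

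Hatching called 2228 genes in vivo and 7 in IVF. A larger spread between IVF libraries is argued against, since their median SD of log2 CPM was 0.785 times that of the in vivo libraries. Fits without 1 of the 4 in vivo libraries leave 1 library in a group and take its spread from the others. They cannot decide whether a single in vivo library is the cause. Fewer genes were called in vivo when the 4 in vivo libraries were fitted alone. IVF had more libraries than in vivo, which by itself favours IVF calls, so cutting its groups could not test library number. At 2 against 2 IVF libraries, the group size in vivo, the 9 choices called at most 7 genes in fits with the 4 in vivo libraries. The gap in calls thus held for each choice of IVF libraries at that size. Over 4511 expressed genes the median absolute log2 fold change was 0.52 in vivo and 0.15 in IVF. Spread between libraries adds to both values, and more in vivo. There the groups had 2 libraries and median SDs of 0.247 and 0.283, against 0.209 and 0.208 in IVF. Part of this gap may therefore be spread. A smaller gap in age between IVF blastocysts and IVF hatched blastocysts than in vivo may contribute and was not tested.

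Mitochondrial messages were lower in IVF than in in vivo embryos at both stages. In blastocysts 12S rRNA (1.56 ± 0.37, adjusted p = 0.0225) and 16S rRNA (1.86 ± 0.62, adjusted p = 0.0763) lay at least 2.92 above the messages' median of -1.36. The 2 in vivo libraries had 19.7 and 88.7 CPM of 16S rRNA. The rRNA counted there did not share the messages' fall. As rRNAs reach a poly(A)-selected library only in part, this cannot decide whether in vivo libraries held more mitochondrial RNA of every kind. In hatched blastocysts that explanation cannot be told apart either. There 12S rRNA (-0.29 ± 0.35) lay above the median of -2.01, but 16S rRNA (-1.35 ± 0.57) lay only 0.66 above it, within 2 standard errors. A single in vivo library is argued against in blastocysts. There the messages' share was 3.52% and 3.76% in vivo and 0.88% to 1.07% in IVF. In hatched blastocysts the unnumbered in vivo library (1.49%) and library 2 (6.85%) both lay above IVF (0.61% to 0.98%). The size of that difference rests largely on library 2. The largest adjusted p of the list by camera without any in vivo library of the stage was 1.26e-05 at the preset correlation. Such fits leave 1 in vivo library in the group, so this p cannot decide the question. A difference in RNA handling between origins stays open.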

How the results depend on the processing

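The fits without mitochondrial genes, with a robust prior and with IVF groups of 2 libraries were added after the data were seen. Below, counts of called genes come in the order IVF against in vivo blastocysts, IVF against in vivo hatched blastocysts, hatching in vivo, hatching in IVF, and the difference of the hatching changes. With DESeq2 they were 2944, 3001, 3562, 51 and 1879, against 1681, 1839, 2228, 7 and 732. DESeq2 made more false calls in simulated data, but those counts were drawn with the spread fitted by edgeR and few changed genes. They do not tell how many DESeq2 calls here are false. Of the 51, 25.5% were higher, against 0 of the 7 with edgeR. Without a filter on low counts, 2749, 2850, 162 and 1855 genes were called in all but hatching in vivo, and the prior degrees of freedom became infinite. With all 13 libraries in 1 fit there were 7, 92, 101, 0 and 1, and the common dispersion rose from 0.276 to 0.633. In the fit of the 9 IVF libraries it was 0.571, and 0.36, 0.514 and 0.515 without 4-cell library 1, 2 and 3. Much of the larger spread thus came with 4-cell library 1. Fitting only the 4 in vivo libraries gave 757 for hatching in vivo, and IVF groups of 2 called 0 to 7 genes at hatching. Leaving out 1 library gave 320 to 1757, 513 to 2068, 1064 to 2153, 4 to 7 and 333 to 969, and 7622 to 11451 and 7511 to 11531 for blastocysts and hatched blastocysts against 4-cell embryos. Some of these fits leave an in vivo group with 1 library, which is assumed to vary like the others. Numbers did not pair the libraries (correlations of deviations from -0.15 to 0.03), and with the replicate number as a block 910, 1088, 1097 and 266 genes were called in all but hatching in IVF. The unnumbered in vivo hatched library is a block of its own, so comparisons with in vivo hatched libraries then rest on library 2. Lists called with an estimated correlation were 0 in 6 comparisons and 1 for hatching in IVF, against 5, 11, 11, 8, 10, 15 and 14. Leaving out 1 library gave 4 to 8 lists for blastocysts and 5 to 10 for hatching in IVF. For the list of genes higher in 4-cell embryos, in blastocysts the adjusted p of 0.814 was 0.914 with the block and 0.127 to 0.763 with 1 library left out, with the sign changing in some, and in hatched blastocysts it was 0.358 with an estimated correlation and 0.00359 to 0.114 with 1 library left out. The list of genes higher later had 0.0776 in blastocysts with an estimated correlation. Genes called at both stages were 487 higher and 300 lower with DESeq2, 157 and 65 with the block, and 74 lower at a fold of at least 2, against 257 and 115. Genes called at hatching in both origins were 5 higher and 19 lower with DESeq2, against 0 and 5. Other counts stayed within 1.5 times. Of the values of named genes under alternatives, 7228 kept direction and call, 686 lost the call, 29 gained one and 50 moved. Of those of lists, 538 kept the call and 130 lost it. No called value changed direction. Where no value above shows a cause, the cause was not tested. Upper-quartile factors moved the median of all genes by -0.10 for hatching in vivo, -0.16 and -0.19 against 4-cell embryos. The alternatives planned for a table without counts did not apply, and limma-trend on FPKM was not run with in vivo hatched libraries. Depth limits genes under 0.0764 to 0.0902 CPM. Low folds were recovered least in simulated data, with shares that do not carry over to these data.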

Other observations

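The tests on X-linked genes and on other splits of the libraries were planned before their results were seen, and the tests by gene family were chosen afterwards. Markers of other cell types gave differences between origins in single genes. FCER1G, known from immune cells, had 113 ± 52.4 CPM in in vivo blastocysts, 14.4 ± 4.22 in in vivo hatched blastocysts, 144 ± 33.4 in IVF blastocysts and 129 ± 6.51 in IVF hatched blastocysts (n = 2, 2, 3 and 3), and its hatching change differed by 2.81 ± 0.45 between origins (adjusted p = 0.00814). The smooth muscle gene MYH11 had 5.83 ± 2.15, 0.471 ± 0.145, 6.14 ± 2.56 and 9.37 ± 2.42 CPM in the same order (difference 4.22 ± 0.69, adjusted p = 0.00919). As both were present in IVF embryos, their presence alone marks no maternal cells here. PECAM1, picked after its values were seen, changed by -2.83 ± 0.67 between hatched blastocysts of the 2 origins (adjusted p = 0.02). Its call was lost without in vivo hatched library 2 (-1.46) or IVF hatched library 2 (-2.50) or 3 (-2.90). The summed cumulus and granulosa markers were at 66.7 and 60.4 CPM in in vivo blastocysts and 286 and 252 CPM in in vivo hatched blastocysts. In IVF they were at 77.9, 211 and 72.8 CPM in blastocysts and 409, 169 and 190 CPM in hatched blastocysts. The rise in vivo came mainly from CYP11A1 (0.202 to 106 CPM), STAR (2.97 to 35.7) and EREG (7.52 to 60.9). In IVF hatched blastocysts these had 87.5, 83.9 and 37 CPM. FSHR, LHCGR, NR5A1 and TNFAIP6 of the same list had no counts in any blastocyst or hatched library. The sums alone therefore mark no cumulus or granulosa cells here.

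Genes grouped by the stem of their symbol gave 147 families. After IVF the annexin family (ANXA) was higher in blastocysts, where 4 of 12 genes rose (adjusted p = 0.0151, adjusted p = 0.933 with an estimated correlation) and in hatched blastocysts, where 3 rose (0.0351, adjusted p = 0.959 with an estimated correlation). In hatched blastocysts the helicase families DDX (6 of 35 genes fell, adjusted p = 0.000291) and DHX (3 of 16, 0.00157), the splicing factors PRPF (2 of 13, 0.0217), the nucleoporins NUP (3 of 22, 0.0425), the deubiquitinases USP (4 of 45, 0.0482) and the chaperones HSPA (4 of 12, 0.0217) were lower after IVF, each with adjusted p = 0.959 with an estimated correlation. With hatching in vivo the DHX family was higher, with 6 of 16 genes rising (0.0144, adjusted p = 0.985 with an estimated correlation).

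Of the 36 lists, 12 passed in none of the 7 comparisons. Their smallest adjusted p were 0.0552 for imprinted genes, 0.116 for fatty acid metabolism, 0.116 for blood and immune cells, 0.136 for the Hippo pathway, 0.137 for pluripotency and epiblast, 0.137 for the interferon response, 0.143 for apoptosis regulators, 0.247 for sperm, 0.319 for stroma and vessel, 0.432 for extracellular matrix and integrins, 0.48 for the hypoxia response and 0.567 for oviduct and uterine epithelium.

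A different sex ratio or X dosage of the embryos was a hypothesis for differences between origins. Over 563 X-linked genes the median log2 fold change of IVF against in vivo lay -0.123 from that of other genes in blastocysts (adjusted p = 0.117) and 0.3 from it in hatched blastocysts (adjusted p = 0.197). X-linked genes fell relative to others with hatching in vivo (-0.353, adjusted p = 0.0376, adjusted p = 0.482 with an estimated correlation), and the 2 hatching changes differed (0.413, adjusted p = 0.0318, adjusted p = 0.482 with an estimated correlation). The 2 stages went opposite ways, which neither outcome set down in advance covers, so these values leave the hypothesis open.

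For the comparisons of 3 with 3 libraries, 10 splits are too few for a share under 0.05, and in each of the 3 comparisons 1 split, the real one, gave as many genes. IVF hatching called 7 genes in the real split and at most 1 in another. Blastocysts against 4-cell embryos called 9185 and hatched blastocysts against 4-cell embryos 9230, and at most 0 in another split by edgeR.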
